A study of Mus musculus with 4 samples.

How the data were processed

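RNA was measured by sequencing in C57BL/6 mouse cells sorted by FACS from fetal liver (2 libraries) and from adult bone marrow (2 libraries). The libraries were made from cDNA of sorted cells with a low-input SMARTer kit, per the labels' protocols. The surface markers or reporters used for the sort are not given in the sources used here. Nothing in the labels says whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Groups were taken from the sample titles. The titles give replicate numbers 1 and 2 for fetal liver and 2 and 3 for bone marrow.

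The data used are 1 table of the comparison between the groups that the authors deposited. GSNAP, HTSeq and DESeq and the genome build mm9 are named in the submitters' processing notes, without versions. The gene annotation and filters the authors used are not given in the sources used here. The deposited table holds, as a normalized read signal, the authors' mean of size-factor-scaled read counts over the libraries of each group, per the file headers. Its fold is the authors' ratio of the fetal liver mean to the bone marrow mean, per the file headers. Its p-value and adjusted p-value columns come from the authors' comparison, per the file headers. The column of log2 fold changes was not used. Of 37996 features, 35605 had reads in at least 1 library and a p-value, and 2391 were at 0 in both groups. A Benjamini-Hochberg adjustment of the deposited p-values put all 35605 features on the same side of 0.05 as the authors' adjusted p-value, and the adjusted values differed by at most 0.550%. A feature was called higher or lower in fetal liver at an authors' adjusted p-value under 0.05, a test chosen before the data were examined for the case that only a table of results was given.

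Gene labels in the deposited table did not stand beside their own values. The table carried 33465 gene labels at its top and 4531 features without a label at its end. The features are sorted by p-value. Features with equal p-values were assumed to be sorted by gene identifier, which the sources used here do not state. Only 69.4% of 9026 adjacent labels with equal p-values stood in ascending order. The labels were therefore placed again by a hidden Markov model in which label order was kept and features without a label could lie anywhere between labels. The model used the identifier order within equal p-values (error rate 0.001) and a score of gene structure against level, bounded at 4. The score was trained with LightGBM 4.6.0 in 5 folds of labels, so that no label was scored by a model trained on it. Features near a held-out label could still serve in training. Gene structure (exonic length, exon number and gene type) was taken from GENCODE M21 on GRCm38, and its coordinates are not printed because the authors' build is mm9. A first form of the score, in which held-out features served only as negative examples, was replaced. Labels had moved by 6 features at label 500, 43 at label 2000, 1534 at label 20000 and 3356 at the last tested label. Of 32237 labels of tested features, 20050 (62.2%) were placed at a posterior of at least 0.95, and a value is printed for a gene only then. A gene value given as in the authors' deposited table is that of the feature where its label was placed. That feature need not be the one beside the label. Among genes called either way, 90.1% were placed. A gene was counted as called where its posterior mass on called features was at least 0.95, and as open where neither outcome reached it. What displaced the labels was not tested. On simulated labels of the same table, 97.8% of placed labels were right over 32237 labels, and 99.6% over 1481 labels of called features. The gene structures paired with levels in that simulation came from the placement itself, so these shares are upper estimates.

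Reads of single libraries were recovered from the group means. Each mean is a sum of whole reads of 2 libraries, each multiplied by what 1 read of that library is worth. For means up to 10000, this gave a single solution for 34525 of 34525 features in bone marrow and 31919 of 31921 in fetal liver. A wrong step, tried only on a subset of features with a mean under 100, gave 1 or more solutions for 20.3% and 15.7%. Higher means had no such control. On simulated means, 100% of 33325 bone marrow features and 99.9% of 31034 fetal liver features were split rightly. The libraries are called deeper and shallower, because the table does not tie them to the replicate numbers. 1 read was worth 0.676 normalized reads in the deeper and 2.86 in the shallower bone marrow library, and 0.379 and 1.19 in the fetal liver libraries. Because these reads were inferred, a second test was added after seeing the data: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(normalized reads + 1), over 16501 features with a mean of at least 10, with Benjamini-Hochberg adjustment. Fold changes with a standard error (SE) come from that fit, and the pseudocount understates the change of low genes. On data simulated for this comparison over 16501 features with 200 changed, at the median dispersion of 0.0370 it recovered 5 of 50 features changed 2-fold, 37 of 50 changed 4-fold, 49 of 50 changed 8-fold and 50 of 50 changed 16-fold, with 3 false calls. At the level-weighted mean dispersion of 0.229 it recovered 0, 3, 10 and 33 of 50, with 0 false calls. An arbitrary dispersion used at first was replaced by these estimates.

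Named genes followed a rule fixed before the data were examined. It took 12 fixed genes (Nes, Cspg4, Cxcl12, Kitl, Lepr, Pdgfrb, Pdgfra, Angpt1, Vcam1, Igf2, Mki67 and Acta2) and the 8 called genes with the largest change in each direction. The latter had a mean in the upper part of the tested features, split at the median of 8.27, and groups that did not overlap, with predicted genes and pseudogenes passed over. It also took from each list the 2 called members of highest mean per direction, or the 2 measured members of highest mean where fewer than 2 were called. Placement at 0.95 was required in addition after the data were seen. Rpl9-ps6, a pseudogene by its symbol that the annotation lists as coding, was passed over after its value was seen. Some genes that the rule takes are not reported here. Other genes named in the text, beyond this rule, were chosen after their values were seen and come from the fixed lists.

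The 40 gene lists were fixed before the data were examined. The 27 program lists covered niche factors, pericyte and mural genes, marrow mesenchymal stromal genes, osteolineage, chondrogenic and adipogenic genes, S phase, G2 and M phase, cell cycle inhibitors, fetal and imprinted growth genes, posterior and anterior Hox genes with limb and visceral transcription factors, arterial and venous genes, collagens and fibrillar matrix, basement membrane, immediate early genes, interferon response, MHC, chemokines and cytokines, the Wnt, Bmp and Tgf-beta, Notch and Hedgehog pathways, glycolysis, oxidative phosphorylation and cytosolic ribosomal proteins. The 13 marker lists covered endothelial, liver sinusoidal endothelial, hepatocyte or hepatoblast, cholangiocyte or epithelial, erythroid, neutrophil, macrophage, B cell, megakaryocyte, pan-leukocyte, hepatic stellate, mesothelial and Schwann or glial cells. For each list the median log2 ratio of group means + 1 over placed members was set against 10000 random lists of the same size matched on mean level in 20 bins. A list was said to lie outside the random lists where its median fell outside their central 95%, as a description with no p-value. With 40 lists, chance alone would put some outside. In simulated data, 7 of 100 lists without a shift and 78 of 100 lists shifted by 1 on the log2 scale lay outside. The simulated genes varied independently, so these shares do not cover lists whose members move together, as bone genes did between libraries. Members past 0.05 after adjusting the authors' p-values over the placed members of a list were counted as adjusted over the list alone. Psmb9, Hbb-b1 and Hbb-b2 were not measured, and the label of Ccl19 lies among features at 0 in both groups.

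Alternatives fixed before the data were examined were other thresholds, a minimum fold, a minimum mean level, recentred ratios, other pseudocounts and leaving out each library. The limma fits, other label placements, folds of group means without each library and library agreement were added after seeing the data. A floor of 3 reads over the group was used for genes at 0 in fetal liver, and it covers counting error only. Whether the authors' counting used strand is not given in the sources used here, so overlapping and antisense genes could not be told apart, and values of ribosomal protein genes with many pseudogene copies are uncertain. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.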

Results

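Transcriptomes were compared between cells sorted from mouse fetal liver, where hematopoietic stem cells expand before birth, and cells sorted from adult bone marrow, their main site after birth. The series concerns a stem cell niche associated with portal vessels of the fetal liver, and the comparison asks how cells sorted from the 2 organs differ in gene expression. Because the sort markers are not given in the sources used here, how far the sorted cells are niche cells is not known. Each group had 2 libraries. In features with means up to 10000 normalized reads, the deeper bone marrow library held 858720 recovered reads and the shallower 223361, and the fetal liver libraries held 2546089 and 868246. The median tested feature had 13 and 3 reads in the bone marrow libraries and 16 and 5 in the fetal liver libraries, so low genes rest on few reads, mainly in the shallower bone marrow library. Between libraries of a group, the median absolute log2 difference was 0.52 in bone marrow and 0.50 in fetal liver over 16501 features with a mean of at least 10. The correlation of log2 values across these features, which are not independent replicates, was 0.665 in bone marrow and 0.807 in fetal liver.

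Fetal liver cells had higher levels of imprinted growth genes (median log2 ratio of the list 3.73), pericyte genes (2.45), ribosomal protein genes (3.82) and genes of mitochondrial respiration (2.64), while few genes were lower. Random lists matched on level were also higher in fetal liver, so these medians are not wholly particular to the lists. The central ranges of the random lists were 0.64 to 2.44, 0.22 to 2.03, 0.98 to 2.60 and 0.73 to 2.29, in the same order. Each list median lay above its range. The hepatoblast genes Alb (21.3-fold) and Afp (25.8-fold) were higher too, and the neutrophil gene S100a9 was lower. These are values in the authors' deposited table of the features where the labels were placed. As the labels stand in that table, S100a9 lies beside a feature that was higher in fetal liver. By the authors' adjusted p-value, 1467 features were called higher and 46 lower in fetal liver, so that 97.0% of 1513 calls were higher. At an unadjusted p under 0.05 the authors' deposited table had 3095 features higher and 853 lower. After placement of the labels, 1436 genes were higher, 40 were lower and 8 were open. Both fetal liver libraries lay above both bone marrow libraries in 1463 of 1463 features called higher with recovered reads, and below in 46 of 46 called lower. Chance gives 16.7% per direction for features not selected by a test, and selection on these same libraries raises it. With limma and Benjamini-Hochberg adjustment on recovered reads, a test added after seeing the data, 3172 features were higher and 474 lower. These included 1452 of the 1467 higher and 30 of the 46 lower calls. None of the authors' calls was called in the opposite direction by limma, but this was fixed in advance. Both tests used the same libraries, and in called features with recovered reads the libraries of the 2 groups did not overlap. Without the shallower bone marrow library limma called 3412 higher and 209 lower, and without the deeper fetal liver library 2522 and 792.

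The 8 largest increases included Itm2a, a transmembrane protein gene, with an authors' mean of 33.9 in bone marrow and 2919 in fetal liver, 86.1-fold, in the authors' deposited table (authors' adjusted p = 0.000642). Col3a1, a fibrillar collagen gene, rose 73.7-fold from 66.1 to 4876 in the authors' deposited table (authors' adjusted p = 2.27e-12). The cytokine gene Mif rose 49.3-fold, Maged2 44.8-fold, the smooth muscle gene Tagln 44.8-fold, the kinase gene Nrk 44.2-fold, Armcx2 42.4-fold and the ribosomal protein gene Rpl36 40.5-fold in the authors' deposited table. Their limma log2 fold changes were 6.59 ± 0.67 (SE, 2 libraries per group) for Itm2a, 6.10 ± 0.80 for Col3a1, 5.23 ± 0.48 for Mif, 5.49 ± 0.46 for Maged2 and 4.96 ± 0.55 for Tagln. Some of these folds depend on which library is used, as folds recomputed after seeing the data without each library in turn showed. Without the deeper and the shallower bone marrow library they were 53.7 and 216 for Itm2a, 32.4 and 72.5 for Maged2 and 28.5 and 98.7 for Nrk, and the shallower one had no read of Armcx2. Without the deeper and the shallower fetal liver library they were 116 and 56.2 for Itm2a and 73.6 and 15.9 for Tagln. The lowest such fold was 2.66 among 105 placed list members and named genes called higher, and in 43 of them the fold moved by over 1.5 times. The deeper and shallower bone marrow libraries stood at 3.38 and 2.86 normalized reads of Mif and 5.40 and 2.86 of Rpl36, where 2.86 is 1 read.

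Genes lower in fetal liver included markers of myeloid cells and a limb patterning gene. S100a9, a calcium-binding protein gene of neutrophils, had an authors' mean of 76.3 in bone marrow and 1.73 in fetal liver in the authors' deposited table (authors' adjusted p = 0.00253), and its limma log2 fold change was -4.60 ± 0.78. Hoxd13, a homeobox gene of the distal limb, went from 34.2 to 1.16 in the authors' deposited table (authors' adjusted p = 0.00288). The largest decreases also held genes at 0 in fetal liver, of which Nfkbid, a regulator of NF-kappaB, was at least 23.8-fold lower. The myeloid receptor gene Clec5a was at least 19.5-fold lower and the neuropeptide gene Hcrt at least 23.7-fold lower, each against 3 reads over the fetal liver group. Fam26d went from 18 to 0.568, Itgbl1 from 28.3 to 1.57 and the gastric proton pump gene Atp4a from 27.7 to 1.57 in the authors' deposited table. With limma and Benjamini-Hochberg adjustment Nfkbid (adjusted p = 0.0822, and 0.00173 with the authors' p-values adjusted over features with a mean of at least 10) and Hcrt (0.125 and 0.0210) were not called, while Clec5a and Fam26d lay under its minimum mean. The deeper and shallower bone marrow libraries stood at 118 and 34.3 normalized reads of S100a9, 10.8 and 22.9 of Clec5a and 9.46 and 31.5 of Hcrt. The fetal liver libraries, in the same order, stood at 1.14 and 0 of Fam26d and at 0.758 and 2.38 of both Itgbl1 and Atp4a. These directions rest on the placement of the labels: as the labels stand in the deposited table, 7 of these 8 genes, Hcrt excepted, lie beside features that were higher in fetal liver.

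**Figure D1:**
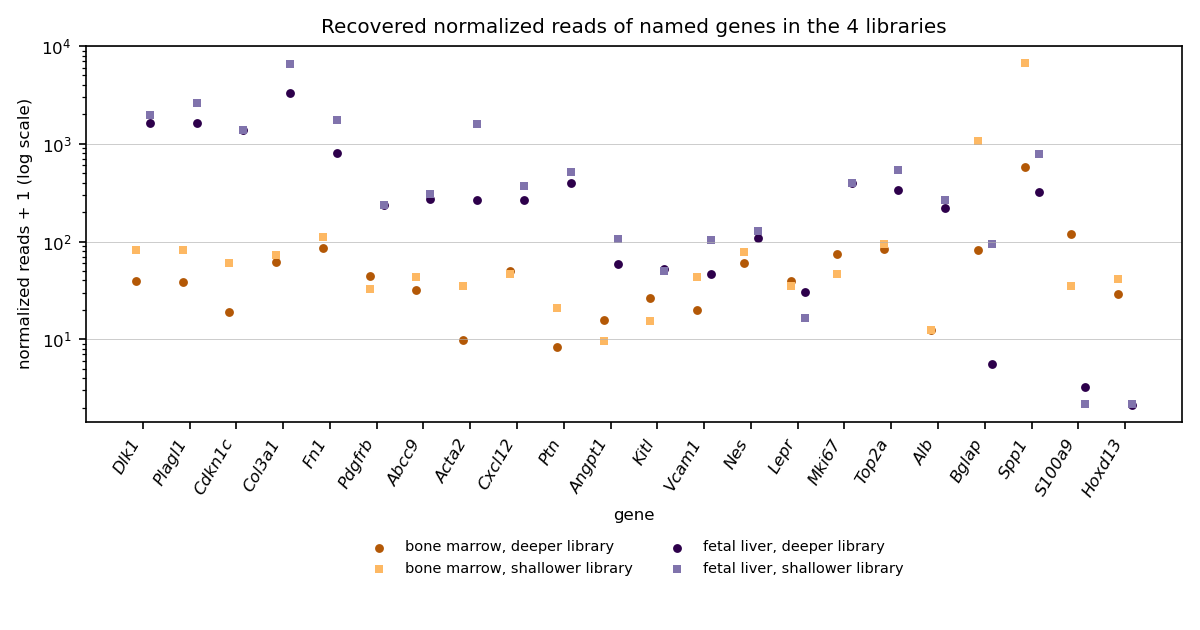
Normalized reads + 1 on a log axis for 22 named genes in each of the 4 libraries, with 1 point per library colored by group. Fetal liver points lie above bone marrow points for genes such as Col3a1, with 3275 and 6477 against 60.8 and 71.5 normalized reads, and below them for genes such as S100a9.

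Niche factor genes, which encode secreted and surface signals for stem cells, had 6 of 18 measured members higher and none lower. Cxcl12, the chemokine that retains stem cells, rose 6.72-fold from 47.2 to 317 in the authors' deposited table (authors' adjusted p = 0.000122), with a limma log2 fold change of 2.70 ± 0.42. Ptn, a secreted growth factor, rose 33.2-fold and Dlk1, an imprinted Notch-related ligand, 30.2-fold in the authors' deposited table. Their folds without the deeper and the shallower bone marrow library were 22.8 and 61.3 for Ptn and 22.4 and 46.5 for Dlk1. Angpt1, a ligand of the Tie2 receptor, rose 6.97-fold (authors' adjusted p = 0.0332) and the Notch ligand gene Jag1 3.57-fold (authors' adjusted p = 0.0215) in the authors' deposited table. The remaining called member, Igf2, an imprinted growth factor gene, was not tied to 1 feature: its 3 candidate features were all called higher, with folds from 55.9 to 158 in the authors' deposited table. Not called were Kitl, the ligand of the Kit receptor (2.51-fold, authors' adjusted p = 0.796), and the adhesion gene Vcam1 (2.41-fold, authors' adjusted p = 0.748) in the authors' deposited table. With limma and Benjamini-Hochberg adjustment, Kitl had an adjusted p of 0.0469 and a log2 fold change of 1.34 ± 0.46, against 0.446 with the authors' p-values adjusted over features with a mean of at least 10. In this list 5 members were higher adjusted over the list alone. Its median log2 ratio of 1.24 was at percentile 87.4 of the random lists. With the labels as they stand in the deposited table, an alternative added after seeing the data, the median turned to -0.99, at percentile 0.26.

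Pericyte and mural genes had 6 of 18 measured members higher, with Heyl open. Pdgfrb, the receptor that marks perivascular cells, rose 6.21-fold from 37.7 to 234 in the authors' deposited table (authors' adjusted p = 0.000718). Abcc9, a potassium channel subunit of pericytes, rose 7.85-fold and the pericyte gene Rgs5 19.9-fold in the authors' deposited table. The smooth muscle actin gene Acta2 had means of 21.5 and 922 but an authors' adjusted p of 0.121 in the authors' deposited table, and its fetal liver libraries stood at 267 and 1578 normalized reads. Limma with Benjamini-Hochberg adjustment gave Acta2 a log2 fold change of 5.13 ± 0.69 (adjusted p = 8.93e-05), against 0.0573 with the authors' p-values adjusted over features with a mean of at least 10. Cspg4, which encodes the pericyte antigen NG2, was not tied to 1 feature and was not called: its 3 candidate features had folds from 0.217 to 2.20 in the authors' deposited table. Of the mural genes, 9 were higher adjusted over the list alone. The median of 2.45 was at percentile 99.8, but with every label at its most probable feature, an alternative added after seeing the data, at percentile 94.4. Hepatic stellate markers, with a median of 2.04, moved with this list.

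Marrow mesenchymal stromal genes had 4 of 18 members higher: Cxcl12, the cadherin gene Cdh11 (7.07-fold), Snai2 (11.8-fold) and Prrx1 (6.01-fold) in the authors' deposited table. For Cdh11 the fold was 5.11 without the deeper and 11.5 without the shallower bone marrow library. The intermediate filament gene Nes, used to mark niche cells, had means of 68.3 and 117 (authors' adjusted p = 0.739) in the authors' deposited table. The leptin receptor gene Lepr had 36.4 and 22.3, and Pdgfra 61.0 and 160.9 (authors' adjusted p = 0.400), in the authors' deposited table, and neither was called. With limma and Benjamini-Hochberg adjustment Pdgfra had an adjusted p of 0.0383, against 0.200 with the authors' p-values adjusted over features with a mean of at least 10. Stromal genes had 4 members higher adjusted over the list alone, and the median of 0.97 was at percentile 62.2. Adipogenic genes had 1 of 13 members higher, the lipid carrier gene Apoe (8.69-fold in the authors' deposited table), also 1 adjusted over the list alone. Their median of 1.56, over only 5 placed members, was at percentile 96.5. It was at percentile 52.75 without the deeper fetal liver library and 71.5 with every label at its most probable feature. The list lay inside the random lists under every setting.

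Imprinted and fetal growth genes had 12 of 20 members higher, also 12 adjusted over the list alone, and a median of 3.73 at percentile 100. Plagl1, a transcription factor of the imprinted network, rose 36.0-fold from 58.9 to 2123 in the authors' deposited table (authors' adjusted p = 1.14e-07). Mest rose from 57.6 to 1438, Peg3 12.7-fold, Meg3 14.4-fold and H19 17.2-fold in the authors' deposited table. Dlk1 had limma log2 fold changes of 4.98 ± 0.61 and Plagl1 of 5.20 ± 0.64. Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, rose 35.4-fold from 39.1 to 1387 in the authors' deposited table. Leaving out the deeper and the shallower bone marrow library gave folds of 23.1 and 76.0 for Cdkn1c, 10.9 and 41.0 for H19, 26.5 and 56.1 for Plagl1 and 17.96 and 40.9 for Mest.

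Cell cycle genes were higher in part. Of G2 and M phase genes, 7 of 20 were higher, with 10 adjusted over the list alone, among them the proliferation marker Mki67 (6.73-fold, authors' adjusted p = 0.000128) and the topoisomerase gene Top2a (4.97-fold, authors' adjusted p = 0.000639) in the authors' deposited table. Of S phase genes, 5 of 20 were higher, with 7 adjusted over the list alone, including the ribonucleotide reductase gene Rrm1 (5.06-fold) and the histone mRNA binding gene Slbp (6.73-fold) in the authors' deposited table. Their medians of 1.55 and 1.46 were at percentiles 91.9 and 95.2 of the random lists. Inhibitors and quiescence genes had 4 of 15 members higher, also 4 adjusted over the list alone, among them Cdkn1c, Gas1 (5.09-fold) and Trp53 (3.79-fold) in the authors' deposited table. Of the inhibitors, 2 were lower at an unadjusted p under 0.05 (0 by limma). The list's median was 0.81 at percentile 69.8. The fold of Gas1 was 3.43 without the deeper and 9.89 without the shallower bone marrow library, and that of Slbp 4.48 and 8.98 without the fetal liver libraries in the same order.

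Of collagens and fibrillar matrix genes, 10 of 22 were higher, including the fibronectin gene Fn1 (13.0-fold, from 98.3 to 1283) and Postn (15.2-fold) in the authors' deposited table. Of basement membrane genes, 6 of 16 were higher, including the type IV collagen genes Col4a1 (13.9-fold, from 99.5 to 1386) and Col4a2 (6.82-fold), and Nid1 (13.7-fold), in the authors' deposited table. Folds without the deeper and the shallower fetal liver library were 17.8 and 8.26 for Fn1 and 19.6 and 7.89 for Nid1, and without the bone marrow libraries in the same order 10.1 and 30.6 for Postn. Counts of 14 and 9 members were higher adjusted over the list alone. The medians of 2.46 and 1.54 were at percentiles 89.0 and 47.8 of random lists with central ranges of 1.42 to 2.71 and 0.68 to 2.42.

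Genes of energy metabolism and translation were higher. Of 18 oxidative phosphorylation genes, 15 rose, among them the ATP synthase gene Atp5b (8.38-fold, from 81.3 to 682) and the cytochrome c oxidase gene Cox4i1 (15.1-fold) in the authors' deposited table. Of 22 cytosolic ribosomal protein genes, 19 rose, among them Rps14 (14.7-fold, from 70.5 to 1035) in the authors' deposited table. Of 17 glycolysis genes, 5 rose, among them the aldolase gene Aldoa (9.91-fold) and the lactate dehydrogenase gene Ldha (5.60-fold) in the authors' deposited table. In these genes the shallower bone marrow library stood above the deeper one. Without the deeper and without the shallower one, the folds were 5.68 and 16.01 for Atp5b, 9.35 and 39.6 for Cox4i1, 9.53 and 31.9 for Rps14, 6.46 and 21.3 for Aldoa and 4.12 and 8.73 for Ldha. Adjusted over the list alone, 17, 14 and 7 members were higher, the count of 14 being over the 16 placed ribosomal members. The medians were 2.64 at percentile 99.8, 3.82 at percentile 100 and 1.41 at percentile 97.6. The glycolysis list no longer lay outside the random lists without the shallower bone marrow library (percentile 77.9), without the deeper fetal liver library (95.3) or with group means + 10 (92.3). It was also inside them with every label at its most probable feature (97.2) and with labels placed at a posterior of at least 0.99 (95.8), alternatives added after seeing the data.

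Patterning genes differed in single members. Posterior Hox and limb genes had 1 of 17 members lower, Hoxd13, also 1 adjusted over the list alone, and a median of -0.30 at percentile 60.4. Anterior Hox and visceral mesoderm transcription factors had 3 of 20 members higher, with 3 higher and 1 lower adjusted over the list alone, and a median of -0.12 at percentile 48.9. The risen members were Hand2 (5.68-fold, authors' adjusted p = 0.00196), Gata6 (5.85-fold, authors' adjusted p = 0.0244) and Tcf21 (14.5-fold, authors' adjusted p = 0.00414) in the authors' deposited table. Gata6 had folds of 8.79 without the deeper and 4.38 without the shallower bone marrow library.

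Vascular identity genes had 1 member each called by the authors' adjusted p-value. Among 14 arterial genes the semaphorin and VEGF receptor gene Nrp1 rose 10.9-fold, and among 10 venous genes the nuclear receptor gene Nr2f2 rose 9.14-fold, in the authors' deposited table. Nr2f2 had folds of 5.90 without the deeper and 20.2 without the shallower bone marrow library. At an unadjusted p under 0.05 each list had 1 placed member higher and 1 lower, and limma also called 1 higher and 1 lower in each, the lower ones being the Notch ligand gene Dll4 (35.9 and 11.3) and the von Willebrand factor gene Vwf (121 and 52.1) in the authors' deposited table. Adjusted over the list alone, 1 member of each was higher. The arterial median of -0.80 was at percentile 0.95 and the venous median of -0.24 at percentile 8.20. The arterial list no longer lay outside the random lists without the shallower bone marrow library (percentile 11.6), without the deeper fetal liver library (9.72) or without the shallower fetal liver library (3.92), or with every label at its most probable feature (3.91).

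Signaling pathways had few called members. In the Wnt list, 2 of 25 rose, the secreted Wnt inhibitor genes Sfrp1 (15.9-fold) and Sfrp2 (7.68-fold) in the authors' deposited table. In the Bmp and Tgf-beta list, 1 of 24 rose, the Bmp target Id2 (8.75-fold, authors' adjusted p = 0.0380), while Id3 had means of 50.9 and 347 and an authors' adjusted p of 0.106 in the authors' deposited table. Limma with Benjamini-Hochberg adjustment called Id3 higher, with a log2 fold change of 3.09 ± 0.55 (adjusted p = 0.000813, against 0.05001 with the authors' p-values adjusted over features with a mean of at least 10). The fold of Id2 was 5.54 without the deeper and 20.7 without the shallower bone marrow library. In the same order these libraries stood at 18.9 and 82.9 normalized reads of Id3. The Notch list had Jag1 higher among 17, with Heyl open, and the Hedgehog list had Gas1 higher among 13 (5.09-fold in the authors' deposited table). At an unadjusted p under 0.05, 1 member was lower in each of the Bmp and Tgf-beta, Notch and Hedgehog lists, and limma called 1 Notch list member lower and 0 in the others. Adjusted over the list alone, 2, 2, 2 and 1 members were higher. The medians were 0.59, 0.49, -0.14 and 0.71, at percentiles 95.6, 69.8, 6.06 and 85.5.

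Of stress and immune genes, 1 was called by the authors' adjusted p-value. Of 20 immediate early genes, Jund rose 4.41-fold in the authors' deposited table (authors' adjusted p = 0.00641), and 3 members were higher adjusted over the list alone. Its fold was 3.20 without the deeper and 7.10 without the shallower bone marrow library. Limma called 4 members higher, and 4 were higher at an unadjusted p under 0.05. The list's median of 1.13 was at percentile 99.8, and at 97.47 (just inside the random lists) without the deeper bone marrow library. By the authors' DESeq comparison, none of 19 interferon response genes was called, with 0 higher and 2 lower at an unadjusted p under 0.05 and none by limma. Their median of -1.11 was at percentile 1.45, but at 6.84 without the deeper and 4.42 without the shallower fetal liver library. Neither MHC genes (0 of 14) nor chemokines and cytokines (0 of 20) held a called member by DESeq. At an unadjusted p under 0.05 the MHC list had 1 member lower and the chemokine list 2 higher, and limma called 1 higher and 1 lower MHC gene and 1 higher chemokine list gene. None of the members of these 3 lists passed adjusted over the list alone. Medians were -0.85 at percentile 3.02 for MHC and 0.09 at percentile 89.7 for chemokines.

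Bone-forming lineage genes had lower median levels in fetal liver, with large differences between libraries. By the authors' DESeq comparison none of 17 osteolineage genes was called, with 1 lower at an unadjusted p under 0.05, and none passed adjusted over the list alone, while limma called 1 higher and 5 lower. The median of -1.53 was at percentile 0, below all random lists. The osteocalcin gene Bglap had means of 574 and 49.2, the bone sialoprotein gene Ibsp 646 and 81.1, and the collagen genes Col1a1 5378 and 3090 and Col1a2 2261 and 4201 in the authors' deposited table. The shallower bone marrow library stood at 1067 normalized reads of Bglap against 81.7 in the deeper one, and at 9999 of Col1a1 against 757. Without the shallower bone marrow library the median was -0.67. Chondrogenic genes had none of 14 members called by DESeq and none adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 2 lower by limma. Their median was -0.22 at percentile 28.3.

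Markers of other cell types that a sort could hold showed liver-related genes in fetal liver and neutrophil genes in bone marrow. Of 12 hepatocyte or hepatoblast genes, 3 rose: the albumin gene Alb (21.3-fold, from 11.5 to 244), the alpha-fetoprotein gene Afp (25.8-fold, from 10.6 to 272) and the apolipoprotein gene Apoa2 (11.6-fold) in the authors' deposited table. Of 10 hepatic stellate genes 4 rose, among them Ptn (33.2-fold), Hand2 (5.68-fold) and Colec11 (5.81-fold) in the authors' deposited table. The bone marrow libraries stood at 18.2 and 2.86 normalized reads of Afp, the latter being 1 read, and its fold was 95.3 without the deeper and 14.9 without the shallower one. For Apoa2 it was 15.8 without the deeper and 7.35 without the shallower fetal liver library. Adjusted over the list alone, 3 and 7 members were higher. The hepatocyte median of 1.61 was at percentile 99.7, and at 96.8 without the shallower bone marrow library. The stellate median of 2.04 was at percentile 98.0, but at 94.1 with group means + 10, 96.7 without the shallower bone marrow library and 96.6 without the deeper fetal liver library, all inside the random lists.

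Of 10 neutrophil and granule genes 1 was lower, S100a9, with 2 lower adjusted over the list alone and a median of -1.19 at percentile 1.91. S100a8, the partner of S100a9, had means of 90.3 and 0.379 (authors' adjusted p = 0.149) in the authors' deposited table. Limma with Benjamini-Hochberg adjustment called S100a8 lower, with a log2 fold change of -5.25 ± 1.21 (adjusted p = 0.00513, against 0.0709 with the authors' p-values adjusted over features with a mean of at least 10), and its bone marrow libraries stood at 166.2 and 14.3 normalized reads. Among 12 endothelial genes, Tie1, an endothelial receptor gene, fell from 43.1 to 8.36 in the authors' deposited table (authors' adjusted p = 0.0314), also 1 adjusted over the list alone, and the median was -0.66 at percentile 3.17. Among 9 B cell genes the transcription factor gene Ebf1, also expressed in marrow stroma, rose 5.71-fold in the authors' deposited table, also 1 adjusted over the list alone, with a median of -0.65 at percentile 28.5. Among 8 mesothelial genes the adhesion gene Alcam rose 7.67-fold in the authors' deposited table, also 1 adjusted over the list alone, with a median of -0.50 at percentile 35.4.

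The remaining marker lists had no member called by the authors' DESeq comparison. At an unadjusted p under 0.05, liver sinusoidal endothelial genes had 2 of 8 lower (2 lower by limma), with Stab2, called lower by limma, at 87.7 and 39.1 in the authors' deposited table, and erythroid genes had 1 of 12 lower (1 lower by limma). Megakaryocyte genes had 1 of 8 lower (2 lower by limma), with Itga2b, called lower by limma, at 67.0 and 23.1 in the authors' deposited table, and pan-leukocyte genes had 1 of 9 lower (0 by limma), which was also lower adjusted over the list alone. Schwann or glial genes had 2 of 8 higher (2 higher by limma). Cholangiocyte (8 measured) and macrophage genes (10 measured) had 0 at an unadjusted p under 0.05 and 0 by limma. No other member of these lists passed adjusted over the list alone. The medians were -0.90 (percentile 5.32) for sinusoidal, -0.53 (21.6) for erythroid, -1.20 (2.04) for megakaryocyte, -0.69 (23.9) for pan-leukocyte, 0.54 (83.4) for Schwann, 0.03 (63.5) for cholangiocyte and -0.48 (43.6) for macrophage genes. The megakaryocyte list no longer lay outside the random lists without the shallower bone marrow library (percentile 7.80), the deeper fetal liver library (19.6) or the shallower fetal liver library (3.30), or with group means + 0.5 (2.78). It was also inside them with every label at its most probable feature (4.84) and with labels placed at a posterior of at least 0.99 (2.83). With the labels as they stand in the deposited table, an alternative added after seeing the data, 7 of the 13 lists outside the random lists lay inside them: pericyte genes at percentile 73.7, osteolineage 57.9, arterial 14.3, immediate early 27.0, interferon response 8.50, glycolysis 30.9 and neutrophil genes 5.64.

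**Figure D2:**
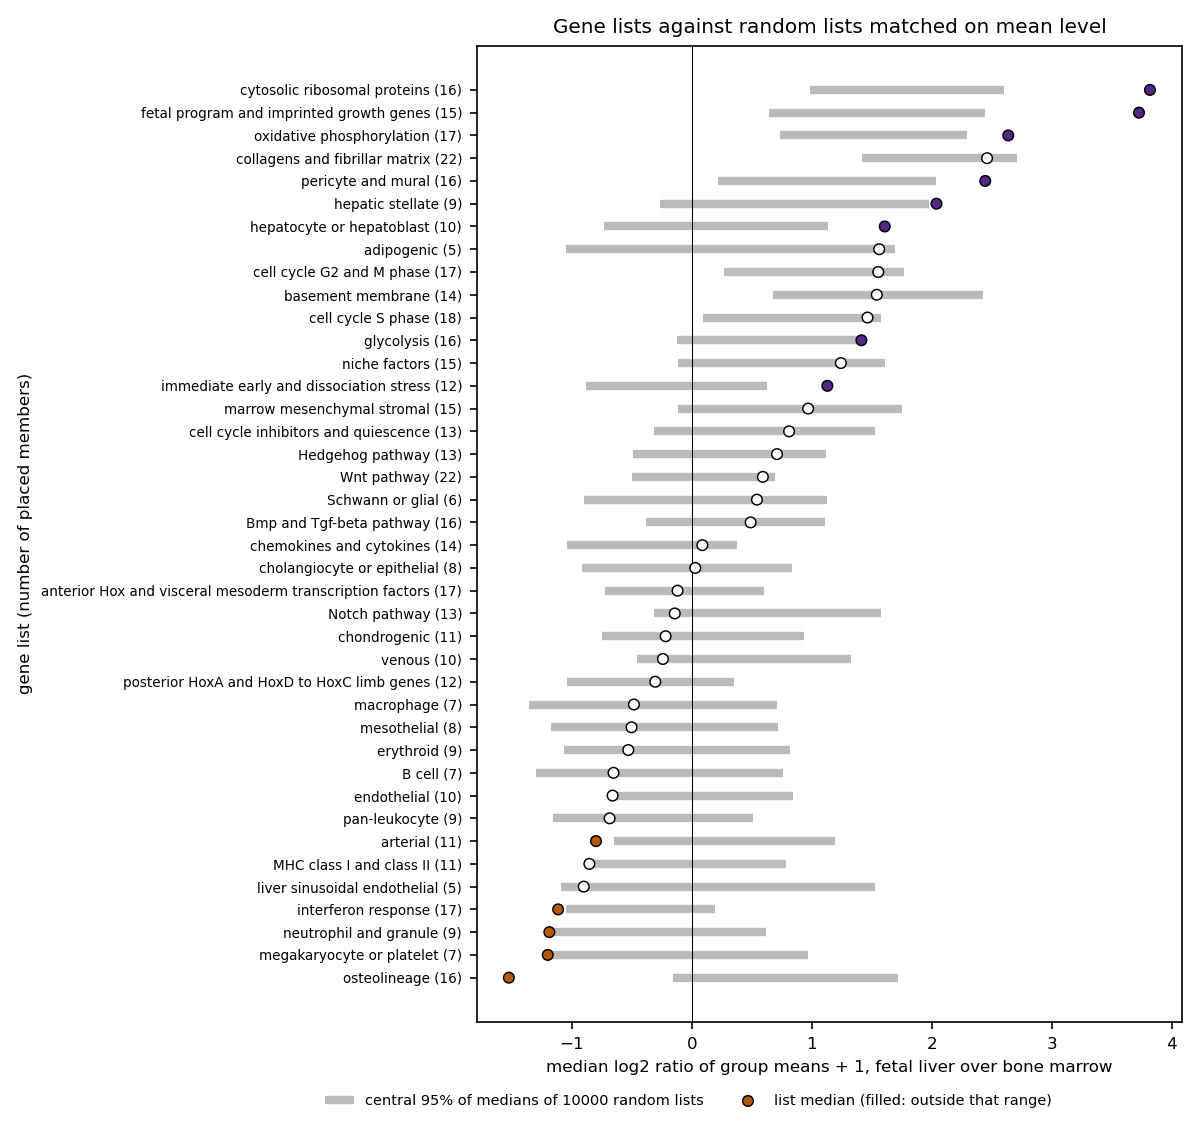
Median log2 ratio of fetal liver over bone marrow for each of 40 gene lists, on group means + 1, as points, with gray bars for the central 95% of 10000 random lists matched on level. Of the 40 points, 13 lie outside their bar, 8 above and 5 below, with the ribosomal list at 3.82 and the osteolineage list at -1.53.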

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

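The tests of the gene labels, of the share of higher calls without each library and of hepatoblast RNA were chosen only after the result was seen, as was the criterion that defines a feature tied to no gene label, which replaced an earlier one that selected only features of low level. Most of the summed means lay in features tied to no gene label, which are those where no label was placed at a posterior of at least 0.95. The largest of these had an authors' mean of 130375511 in bone marrow and 40885155 in fetal liver, a fold of 0.314 (authors' adjusted p = 1) in the authors' deposited table, and took 75.3% and 67.9% of the summed means. The second had 29174479 and 13263360, a fold of 0.455 (authors' adjusted p = 0.708) in the authors' deposited table, or 16.8% and 22.0%. In all, 15555 tested features were tied to no label in this sense and held 97.1% of the summed bone marrow means and 96.9% of the summed fetal liver means. Tested features outnumbered their labels by only 3368, so most of the 15555 have a label whose place is uncertain. Whether the 2 largest are genes or summary categories of the read counter, such as reads assigned to no gene, is not given in the sources used here, so their values are not read as expression.

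The first pattern weighed was that gene labels stood out of step with the values. Features with equal p-values were assumed to be sorted by gene identifier. Labels standing beside their own values would then leave at least 95% of adjacent labels with equal p-values in ascending order. Of 9026, 69.4% did, against 61.6% of adjacent labels with different p-values. Labels closed up over features without a label could account for this: placed by identifier order alone, 4366 labels gave a correlation of exonic length with bone marrow level of 0.661 across genes, against 0.0925 at 100 features away and 0.114 as deposited. No biological explanation was tested for this pattern, because the design gives none. Whether any single label is right stays open, within the placement probability of 0.95.

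The second pattern was that 97.0% of called features were higher in fetal liver. The authors' share of 97.0% was not recomputed without a library, so whether a single library is its source stays open. Of limma calls on recovered reads 87.0% were higher, and leaving out each library in turn gave shares from 76.1% to 94.2%. For the limma calls alone, this argues against a single library as the source of the excess of higher calls. Scaling of the groups against each other stays open, since recentring by 0.05 on the log2 scale left 97.0% of the calls higher but could not have turned any call, the smallest log2 ratio of a call being 1.41 in size, and the finding that both fetal liver libraries lay above both bone marrow libraries in 100% of called-higher features with recovered reads says little, since the features were selected on these libraries. Background reads in the bone marrow libraries cannot be told apart from a difference in expression. Olfactory receptor genes were taken as silent in these cells. In bone marrow they stood at 26.6% of the median level per kb of coding genes (31.03% in the deeper, 18.2% in the shallower library). In fetal liver they stood at 14.8% (13.6% and 8.94%). Their median was 1.53 normalized reads per kb in bone marrow and 0.795 in fetal liver, and 99.7% and 94.9% of them had reads. If they are silent, background was present in both groups and higher in bone marrow. The 26.6% lay between the bounds set before the data were examined, so the check does not decide how much of the pattern background explains. Only 356 of 885 olfactory receptor labels were placed. The difference between fetal liver and adult bone marrow cells that the labels name may also account for the pattern and was not tested apart from it.

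The third pattern was liver cell transcripts in the fetal liver libraries. RNA of hepatoblasts in the sorted cells may be present: 60% of 10 placed hepatocyte or hepatoblast genes were at least 2-fold higher, among them Alb with 220 and 267 and Afp with 260 and 285 normalized reads in the fetal liver libraries. It cannot be told apart from expression by the sorted cells themselves, which would raise the same genes, and of the 5 most abundant placed members 1 had a lower mean, Hnf4a, at 0.735-fold with a limma log2 fold change of -0.06 ± 0.68, which does not decide it. The choice of the 5 most abundant was made after the test was written, and the sort, whose markers are not given in the sources used here, could remove hepatoblasts.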

How the results depend on the processing

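The limma fits, the other label placements, the folds without each library and the counts of library agreement were chosen only after the result was seen. The 1467 higher and 46 lower calls all were at least 2-fold, so that recentring by 0.05 on the log2 scale could turn none. The counts were 964 and 9 at an adjusted p under 0.01, 1803 and 106 under 0.1, and 1817 and 83 when adjusted over features with a mean of at least 10, where fewer features were tested. Limma on recovered reads gave 3172 and 474, 3018 and 403 with a pseudocount of 0.1, 3495 and 744 with 10, and 2696 and 293 with no filter, and the cause was not tested. Limma called 3113 and 283 without the deeper and 3412 and 209 without the shallower bone marrow library, and 2522 and 792 without the deeper and 2389 and 681 without the shallower fetal liver library. These fits assume that the lone library varies like the other group. Lists outside the random lists numbered 13, and 10 to 16 under the other settings, or 9 to 17 leaving out 1 library, of which 8 to 12 were among the 13. With the labels as they stand in the deposited table, 16 lists lay outside, 6 of them among the 13, and the pericyte, osteolineage, arterial, immediate early, interferon, glycolysis and neutrophil lists did not. The 10 gained lay below for niche factors, inhibitors and the Bmp and Tgf-beta pathway and above for chondrogenic genes, S phase, G2 and M phase, collagens, basement membrane, endothelial and sinusoidal endothelial genes. Lists that lay inside with all libraries but outside without 1 of the libraries were S phase, G2 and M phase, collagens, chemokines, Wnt, Notch, endothelial, sinusoidal endothelial and pan-leukocyte genes. The endothelial list also lay outside with group means + 10 and the chemokine list with a minimum mean of 10. So did the sinusoidal endothelial list with every label at its most probable feature (percentile 0.96). With the labels as they stand, the median of the immediate early list was -0.42, and the log2 ratios were 2.56 for Nfkbid, 2.79 for Clec5a, 4.19 for S100a9, 2.38 for Fam26d, 3.18 for Hoxd13, 1.96 for Itgbl1 and 2.78 for Atp4a. These reversals come from reading another feature for each gene. Of 97 named genes, 71 kept direction and call with those labels and 19 moved. By limma 79 of 95 named genes kept direction and call, 13 were called in addition, 2 were no longer called and 1 moved. No paired analysis was possible because the groups share only replicate number 2 and the columns carry no replicate number. The main test planned for a table of counts per sample was edgeR, which was not run on the recovered reads. DESeq2 and the other scaling of counts, planned for such a table, were not run on them either. A gene set test with an estimated correlation was not run. The shallower bone marrow library, where 1 read was worth 2.86 normalized reads, limits what can be seen in low genes.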

Other observations

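The values given here were chosen only after the result was seen, and the differences between libraries were not tested. Except for Dmp1, the bone genes named first differed by more between the bone marrow libraries than between the group means. The shallower bone marrow library held 13.0 times as many normalized reads as the deeper one for Bglap, 12.4 times for Ibsp, 12.7 times for the collagenase gene Mmp13, 11.8 times for Spp1, 13.2 times for Col1a1 and 5.47 times for the osteocyte gene Dmp1. In the fetal liver libraries the same ratio was 20.7 for Bglap, 6.02 for Ibsp, 5.10 for Mmp13, 2.41 for Spp1, 2.89 for Col1a1 and 5.49 for Dmp1. The transcription factor gene Sp7 had 24.3 and 25.7 normalized reads in the deeper and shallower bone marrow libraries but 4.55 and 20.2 in the fetal liver libraries, and the parathyroid hormone receptor gene Pth1r 16.2 and 17.2, and 45.1 and 49.9. For Col1a2 the ratio of the shallower to the deeper library was 12.4 in bone marrow and 2.08 in fetal liver, and for Bglap2 9.95 and 10.8.

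Some list members outside the naming rule also rose. The replication clamp gene Pcna rose 7.42-fold (authors' adjusted p = 0.000396) in the authors' deposited table. The cyclin-dependent kinase gene Cdk1 rose 7.15-fold (authors' adjusted p = 0.000191) and the mitochondrial subunit gene Ndufa4l2, a marker of pericytes, 22.0-fold (authors' adjusted p = 2.62e-05) in the authors' deposited table. Another perivascular gene, Mcam, rose 4.99-fold in the authors' deposited table (authors' adjusted p = 0.000761).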
